A study of Mus musculus with 6 samples.

How the data were processed

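RNA was measured in naive CD4 T cells of mice, sorted from spleen and peripheral lymph nodes as CD4-positive, CD25-negative cells with low CD44 and a further naive-cell surface marker. Per the labels' protocols, the cells descended from blood stem and progenitor cells that carried floxed Tet1, Tet2 and Tet3 and a tdTomato reporter. Those cells had been transduced with a retrovirus encoding CreER, a recombinase that acts once tamoxifen is given, and had been transplanted into wild-type mice irradiated with 10.5 Gy. The mice drank neomycin at 2 mg/ml for 3 weeks. After 2 months they received 3 doses of tamoxifen or of oil, and cells were taken 2 weeks after the first dose. The tamoxifen cells were sorted as tdTomato positive and the oil cells as tdTomato negative. The drug, the reporter gate and Cre activity therefore vary together. There were 6 libraries, 3 per group. Nothing in the labels says that replicates came from separate mice, so p-values measure the spread between these samples, which may be technical.

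Per the labels' protocols, libraries were made from polyadenylated RNA with a stranded kit. STAR, RSEM and the build mm10 are named in the submitters' processing notes, with no version and no stated role. The annotation release is not given in the sources used here. The deposited table holds expected counts per gene, not scaled to depth. Of its values, 7.2% were not whole numbers, and they were rounded before testing. The table had 55573 genes and 92 spike-in rows, which were 0 in every library. Of the gene IDs, 55480 matched GENCODE M21 (GRCm38) without the version suffix, and coordinates and GC content come from that annotation. Where a symbol had several IDs, the one with the highest total count was used. The authors' expected counts can split reads between near-identical copies, such as the haemoglobin genes and the Hspa1a and Hspa1b pair, so these values are uncertain per gene.

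Library totals ran from 48338779 to 66002143 expected counts. A count of 0 allows up to 3 counts, which is 0.0455 to 0.0621 CPM depending on the library, and this covers counting error only. No pair of libraries agreed within sampling noise, since the chi-square statistic per degree of freedom was 32.6 or more for each pair. CPM, counts scaled to the library size with TMM factors, were computed here from the deposited counts.

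Genes were tested with edgeR 4.0.16 in R 4.3.3 by a two-sided quasi-likelihood test with a robust fit, after filterByExpr with its defaults and TMM normalization, with group as the sole term. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. Fold changes are tamoxifen over oil throughout.

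The 26 lists of genes, the main tests and the wording of the rule for named genes were fixed before the data were examined. Lists of red cell precursor, memory and effector, and structural T cell genes, and the tests that use them, were added after results were seen. The first 26 held 516 entries, of which 7 were not matched in the table. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists. The tests were repeated with the correlation estimated from the data and with fry, which tests whether the members of a list move one way without comparing them with other genes. The rule named Tet1, Tet2 and Tet3 and, where no gene passed the threshold, the 5 genes of smallest p in each direction. These were taken among named genes with a mean of at least 2 CPM and no overlap between the groups, a reading of the rule made when no gene had passed. It also took up to 4 members of each list by p, and the 3 most abundant members of lists of other cell types. The text gives part of these, some genes that the rule names are not reported here, and members chosen after their values were seen are said to be so.

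Alternatives were RLE and upper quartile factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a non-robust fit, the replicate number as a block, leaving out each library, and leaving out mitochondrial, immunoglobulin, haemoglobin and most abundant genes. A test against a log2 fold change of 0.5 (glmTreat) was also run. A GC correction was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

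The tests were tried on simulated counts for tamoxifen against oil, 3 against 3, with 200 genes changed. edgeR recovered 65% of genes changed 2-fold and 89% of those changed 4-fold, with 15 false calls among 15051 genes. DESeq2 recovered 80% and 95%, with 65 false calls among 15349 genes, and limma-voom 54% and 87%, with 9 false calls among 15051 genes. Set against calls, the 65 false calls of DESeq2 stood beside 80 and 95 true ones, and the 15 of edgeR beside 65 and 89. Genes were simulated independently of each other, and the changed ones had a mean of at least 2 CPM. In the real libraries genes move together, with an estimated correlation of 0.794 for the cell cycle list. These rates therefore need not hold for the data.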

Results

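Gene expression was measured by RNA sequencing in sorted naive CD4 T cells after oil (3 libraries) or tamoxifen (3 libraries). Tamoxifen was given to switch on Cre in cells carrying floxed alleles of the 3 TET genes, whose enzymes oxidize methylated cytosine in DNA. Total expected counts were 66002143, 48462743 and 50637052 in the oil libraries and 58490581, 55628908 and 48338779 in the tamoxifen libraries. The series' title asks how ascorbate and TET enzymes set the responsiveness and the tolerance of naive T cells, and ascorbate was not analysed here.

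The targeted genes came first, as a check of the labels. Tet1 (ENSMUSG00000047146.17, chromosome 10, 62804570 to 62908996, GRCm38) had 35.5 ± 4.84 CPM (SD, n = 3) in oil and 22.7 ± 3.08 CPM (SD, n = 3) in tamoxifen, with every tamoxifen library below every oil library. Its log2 fold change was -0.65 (SE 0.14), which missed the threshold in edgeR (adjusted p = 0.257) and passed it in DESeq2 (adjusted p = 0.0102). Tet3 (ENSMUSG00000034832.15, chromosome 6, 83362373 to 83459084) was the most abundant of the 3, with 199 CPM in oil and 165 CPM in tamoxifen (log2 fold change -0.27, SE 0.15, edgeR adjusted p = 0.492). Tet2 (ENSMUSG00000040943.12, chromosome 3, 133463679 to 133545139) had a log2 fold change of 0.18 (SE 0.21, edgeR adjusted p = 0.766), which was -0.0035 without oil replicate 2. Counts over whole genes take in exons outside a deleted part, so these values check the deletion only in part.

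No gene passed the adjusted threshold in edgeR among 15349 tested, in either direction, and the lowest adjusted p was 0.101. At an unadjusted p under 0.05 there were 2145 genes, 1199 higher and 946 lower, where uniform p-values would give 767 and the other 9 splits of the libraries into groups of 3 gave 50 to 1301. limma-voom also gave 0 genes, with 2214 at an unadjusted p under 0.05, while DESeq2 gave 490 higher and 218 lower. The groups did not overlap for 3349 genes, or 21.8%, where chance gives 10% for 3 against 3.

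The genes nearest the threshold on the higher side were Gstm5, a glutathione transferase, and Angptl2, a secreted angiopoietin-like protein. Gstm5 had 0.269 CPM in oil and a log2 fold change of 4.19 (SE 0.37, edgeR adjusted p = 0.101). Angptl2 had 1.05 ± 0.201 CPM in oil and a log2 fold change of 2.39 (SE 0.23, edgeR adjusted p = 0.101). Ddit4, an inhibitor of mTORC1 signalling, followed at 0.95 (SE 0.10), Gpm6b at 1.93 (SE 0.21) and Cebpa, a myeloid transcription factor, at 2.61 (SE 0.30), each with an edgeR adjusted p of 0.151. Without a filter on low counts, Gstm5, Angptl2, Ddit4 and Cebpa passed in edgeR, and all 5 passed in DESeq2 (adjusted p at most 6.12e-09 each, the value of Ddit4). On the lower side, the smallest p-values belonged to Hs3st3b1 at -0.58 (edgeR adjusted p = 0.207) and to Zhx2 at -0.59 (edgeR adjusted p = 0.240). Tagap, a GTPase-activating protein of T cells, had -0.73 and Zrsr1 -0.66, each with an edgeR adjusted p of 0.255. These 4 passed in DESeq2, with an adjusted p of 3.84e-06 for Hs3st3b1, 1.56e-06 for Zhx2, 3.5e-06 for Tagap and 0.000164 for Zrsr1.

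**Figure D1:**
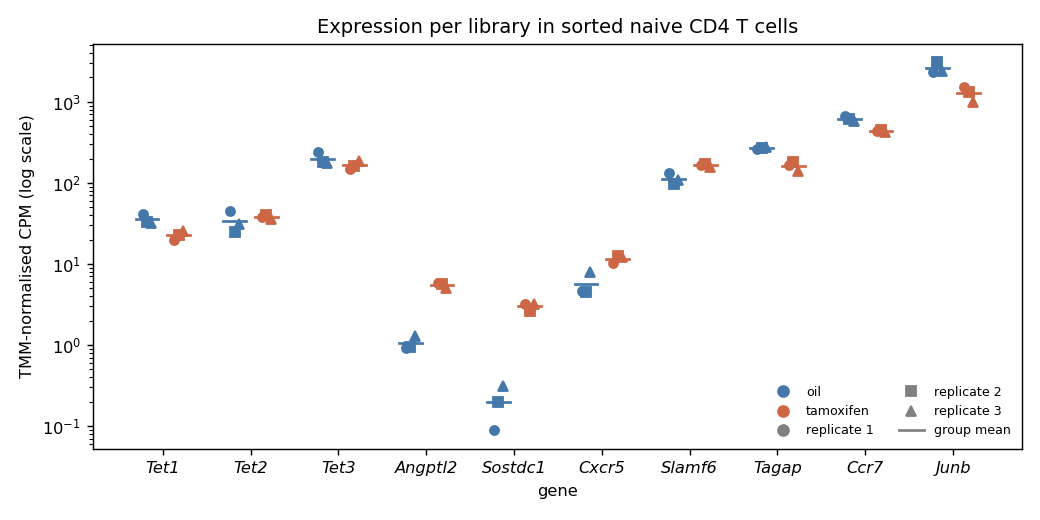
TMM-normalised CPM on a log scale for 10 genes, with one point per library (3 oil, 3 tamoxifen) and a line at each group mean. Angptl2 sits at 0.927 to 1.28 CPM in oil and 5.06 to 5.76 CPM in tamoxifen.

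Of the 26 lists, 11 shifted up and 5 down in camera with the preset correlation. None did with the correlation estimated from the data (lowest adjusted p = 0.161), although 7 had an unadjusted p under 0.05 there.

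Genes of follicular helper T cells, which help B cells in germinal centres, shifted up as a list (14 tested, median log2 fold change 0.97, camera adjusted p = 9.14e-14). The adjusted p was 0.161 with an estimated correlation and 0.0403 in fry, the one list to pass there. That fry call ended without oil replicate 1 or 2, or tamoxifen replicate 1, 2 or 3, where the adjusted p was 0.205, 0.233, 0.117, 0.181 and 0.138. Adjusted over the list alone, 7 of the 14 passed, against 0 over all genes tested in edgeR, and 10 were higher in every tamoxifen library than in every oil library. The count over all genes tested was 6 in DESeq2 and 2 with no filter. The count of 7 was 11 without oil replicate 3, 2 without tamoxifen replicate 2 and 3 without tamoxifen replicate 1 or 3. Sostdc1, a secreted antagonist of BMP and Wnt signals, had 0.0883, 0.195 and 0.309 CPM in oil and 3.20, 2.63 and 3.20 CPM in tamoxifen (log2 fold change 3.94, SE 0.46). Cxcr5, the receptor that guides cells to follicles, had 1.05 (SE 0.25) and the signalling receptor Slamf6 0.55 (SE 0.13). Chosen after their values were seen, Bcl6, the transcription factor that defines these cells, had 0.13 (SE 0.11), and the cytokine gene Il21 had 2.18 (SE 0.85). Oil replicate 3 had a list score of 3.11 mean log2 CPM, against 2.26 and 2.34 in the other oil libraries and 3.89 to 3.92 in tamoxifen.

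Genes of anergy, exhaustion and inhibitory receptors shifted up (24 tested, median 0.37, camera adjusted p = 0.000953). The adjusted p was 0.161 with an estimated correlation, and 0 members passed adjusted over the list alone, with 9 without oil replicate 3, 7 in DESeq2 and 5 in limma-voom. The median was 0.22 without oil replicate 2, 0.62 without oil replicate 3, 0.60 in limma-voom and 0.56 with the replicate block. Of the members, 19 had positive and 5 negative values, with 7 higher and 2 lower in every tamoxifen library than in every oil library. Rnf128, a ubiquitin ligase linked to anergy, had 2.02 (SE 0.45), at means of 0.163 CPM in oil and 0.667 CPM in tamoxifen. Tox2 had 1.76 (SE 0.56), and Nt5e, which encodes CD73, 0.81 (SE 0.28). Tox2 and Pdcd1 are also in the follicular helper list, so the shifts of these lists are not independent. Helper lineage genes also shifted up (14 tested, median 0.53, camera adjusted p = 0.016), with an adjusted p of 0.394 with an estimated correlation. Their median was 1.19 without oil replicate 3. The score of this list was 2.217 mean log2 CPM in oil replicate 3, within the 2.102 to 2.362 of tamoxifen, against 1.385 and 1.147 in the other oil libraries. It was not tested against a memory and effector score. Maf, which the follicular helper list also holds, had 0.89 and Ccr4 1.47, while Gata3, a Th2 regulator, had -0.43.

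Genes of naive identity and quiescence shifted down (24 tested, median -0.20, camera adjusted p = 6.01e-07; adjusted p = 0.161 with an estimated correlation). Adjusted over the list alone, 1 passed, and 22 of the 24 had negative values. That count was 6 without oil replicate 1, 7 in DESeq2, and 0 without any other single library, with upper quartile factors or after GC correction. Ccr7, the lymph node homing receptor, had 623 ± 43.2 CPM (SD, n = 3) in oil and -0.51 (SE 0.10). Klf2, a regulator of quiescence and trafficking, had -0.43 (SE 0.11), Btg2 -0.25 (SE 0.08) and Btg1 -0.39 (SE 0.13).

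Genes induced by or tuned to T cell receptor signals shifted down (21 tested, median -0.28, camera adjusted p = 1.30e-05), with an adjusted p of 0.161 with an estimated correlation, and 2 passed adjusted over the list alone. That count was 8 without oil replicate 1, 4 without tamoxifen replicate 1, 3 without oil replicate 3, and 1 without oil replicate 2 or tamoxifen replicate 2 or 3, with 7 in DESeq2 and 6 after GC correction. Besides Tagap, Myc had -0.56 (SE 0.11) and Cd6 -0.44 (SE 0.12), whereas Spry1, a brake on receptor signalling, had 0.60 (SE 0.17). Proximal signalling genes shifted down (34 tested, median -0.17, camera adjusted p = 0.000362), with an adjusted p of 0.312 with an estimated correlation and 0 passing adjusted over the list alone. Without oil replicate 1 their median was -0.11 and 5 passed adjusted over the list alone, as did 4 in DESeq2. The kinases Lck, Fyn and Csk had -0.34, -0.32 and -0.28, and the phosphatase Ptpn6 had -0.31. Cytokine receptor and survival genes shifted down (30 tested, median -0.20, camera adjusted p = 0.000487; adjusted p = 0.161 with an estimated correlation). Their median was -0.08 without oil replicate 1. Tgfbr2 had -0.43, Stat6 -0.37 and Stat5a -0.38, while the survival gene Bcl2l1 had 0.79. Bcl2l1 had 34.9, 18.3 and 32.1 CPM in tamoxifen and 15.2 to 17.9 CPM in oil. Like haemoglobin, it was near the oil level in tamoxifen replicate 2. A list of 12 structural T cell genes, added after results were seen, had a median of -0.137 and a mean of -0.0916. The lists of this paragraph were not tested apart from a lower share of T cells.

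Early response and stress genes shifted down in camera (25 tested, median -0.38, camera adjusted p = 0.00045; adjusted p = 0.345 with an estimated correlation). Their mean was just -0.0167. The list score overlapped between groups, at 6.3, 6.375 and 6.857 mean log2 CPM in oil and 6.744, 6.653 and 6.293 in tamoxifen. Adjusted over the list alone, 7 passed. That count was 4 without oil replicate 3, 0 without oil replicate 2, tamoxifen replicate 2 or tamoxifen replicate 3, and 1 with upper quartile factors or the filter of 1 CPM. The members did not go one way: Junb had -1.03 (SE 0.20) and Jun -0.66 (SE 0.15), both AP-1 subunits, while the heat shock genes Hspa1b and Hspa1a had 2.39 (SE 0.66) and 2.81 (SE 0.78). The call ended without oil replicate 3 (median -0.25, camera adjusted p = 0.126), and the median was -0.24 without tamoxifen replicate 3.

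**Figure D2:**
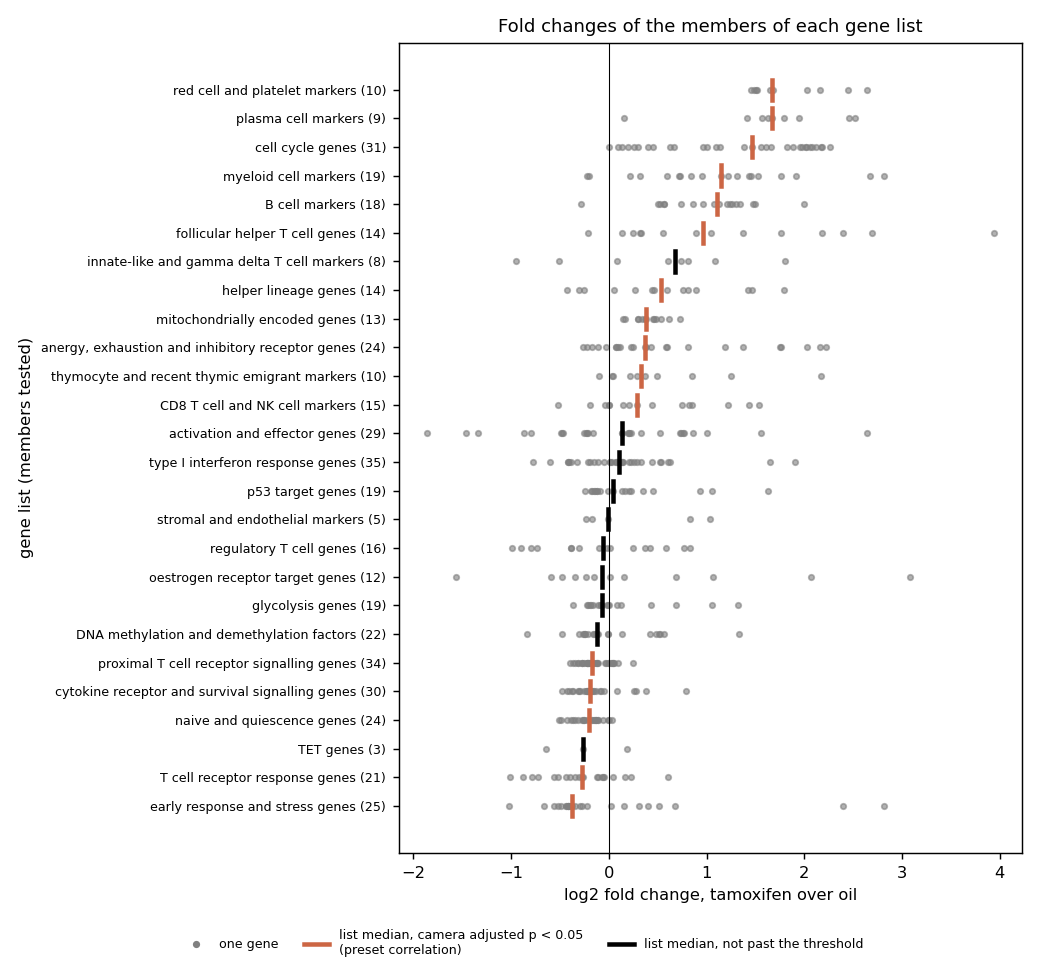
Log2 fold changes (tamoxifen over oil) of the tested members of the 26 gene lists, one grey point per gene, with a bar at each list's median. Bars are coloured where camera with the preset correlation gave an adjusted p under 0.05, and medians run from -0.38 to 1.66.

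Cell cycle genes shifted up (31 tested, median 1.47, camera adjusted p = 3.17e-22), with an adjusted p of 0.240 with an estimated correlation, which was 0.794 for this list. All 31 had positive values, and 26 passed adjusted over the list alone. That count was 0 without oil replicate 1, oil replicate 2, tamoxifen replicate 1 or tamoxifen replicate 3, and 1 with no filter. Nusap1, Ube2c and Birc5, genes of mitosis, had 2.26, 2.17 and 2.18, and Stmn1 had 0.96. Markers of other cells moved with the same group. Red cell and platelet markers shifted up (10 tested, median 1.66, camera adjusted p = 1.06e-07; adjusted p = 0.161 with an estimated correlation), with Hba-a1 at 2931, 1158 and 4062 CPM in tamoxifen and 555, 1094 and 947 CPM in oil. Haemoglobin took 0.25%, 0.56% and 0.468% of counts in oil and 1.3%, 0.546% and 2.09% in tamoxifen.

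Plasma cell markers shifted up (9 tested, median 1.66, camera adjusted p = 6.54e-09; adjusted p = 0.161 with an estimated correlation), and their median was 1.09 without tamoxifen replicate 3. Jchain, which joins secreted antibody, had 76.5, 130 and 241 CPM in tamoxifen and 25.6 to 29.4 CPM in oil. B cell markers shifted up (18 tested, median 1.10, camera adjusted p = 1.06e-07; adjusted p = 0.345 with an estimated correlation), with a median of 0.57 without tamoxifen replicate 3. Igkc had 2.00 (SE 0.46) and Ighd 1.21 (SE 0.32), while Cd74 had -0.29 (SE 0.54). Myeloid markers shifted up (19 tested, median 1.14, camera adjusted p = 5.7e-05; adjusted p = 0.271 with an estimated correlation), with a median of 0.42 without tamoxifen replicate 1. S100a9, a neutrophil gene, had 1637 CPM in that library and 13.7 to 227 CPM in the others.

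**Figure D3:**
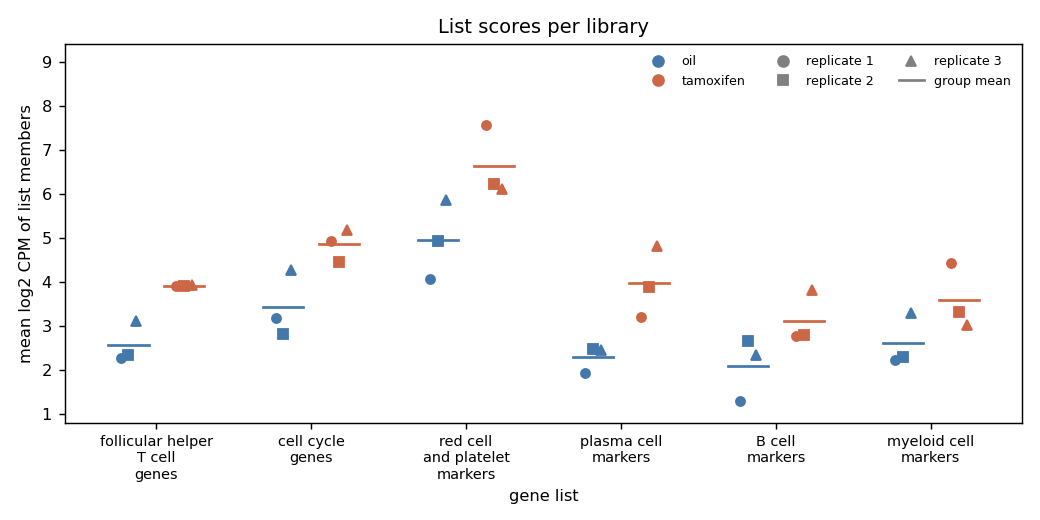
Mean log2 CPM of the tested members of 6 gene lists, one point per library, with a line at each group mean. The follicular helper score is 2.26, 2.34 and 3.11 in oil and 3.89 to 3.92 in tamoxifen.

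Thymocyte and recent emigrant markers shifted up (10 tested, median 0.33, camera adjusted p = 0.0155; adjusted p = 0.183 with an estimated correlation), with a median of 0.62 without oil replicate 2, and Cd24a, also a red cell precursor gene, had 2.17 (SE 0.69). CD8 and NK cell markers shifted up (15 tested, median 0.28, camera adjusted p = 0.0418; adjusted p = 0.345 with an estimated correlation). That call ended with upper quartile factors and without oil replicate 1, tamoxifen replicate 2 or tamoxifen replicate 3, where the median was 0.33, 0.09, 0.25 and 0.35 and the camera adjusted p 0.0572, 0.349, 0.0907 and 0.169. The median of the CD8 and NK list was 0.92 without oil replicate 3, 0.62 in limma-voom and 0.56 with the replicate block. Mitochondrially encoded genes shifted up (13 tested, median 0.38, camera adjusted p = 0.000373; adjusted p = 0.391 with an estimated correlation). Their median was 0.66 without oil replicate 1, 0.21 without oil replicate 2 and 0.25 after GC correction.

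The other 10 lists did not pass in camera. The TET genes had a median of -0.27 (adjusted p = 0.0653). They passed without oil replicate 2 (adjusted p = 0.013), without tamoxifen replicate 3 (adjusted p = 0.0226), with no filter (adjusted p = 0.0325) and in DESeq2 (adjusted p = 0.0276). With an estimated correlation the first 3 of these gave 0.332, 0.439 and 0.360, and it was not run for DESeq2. Their median was -0.11 without oil replicate 1. Activation and effector genes had a median of 0.14 (adjusted p = 0.0519), where Itgb1 had 0.86 and Cxcr3 1.55 but Runx3 -0.50. Their median was -0.08 without oil replicate 2 and 0.35 without oil replicate 3, where they passed, as they did in several other alternatives, but none of these calls held with an estimated correlation where it was run (adjusted p = 0.176 without oil replicate 3). Regulatory T cell genes had a median of -0.06 (adjusted p = 0.634), with Foxp3, the regulator that defines those cells, at -0.90 (SE 0.27). They passed without oil replicate 2 (median -0.10, adjusted p = 0.00786, or 0.207 with an estimated correlation), and their median was 0.17 without oil replicate 3. Type I interferon response genes had 0.10 (adjusted p = 0.400), but passed at 0.26 without oil replicate 3 and at 0.16 without tamoxifen replicate 3, with adjusted p of 0.338 and 0.690 there with an estimated correlation. The p53 targets had 0.04 (adjusted p = 0.634). Innate-like and gamma delta T cell markers had 0.67 (adjusted p = 0.105), with 0.26, 0.39 and 0.36 without oil replicate 1, tamoxifen replicate 1 and tamoxifen replicate 3, and 1.38 without oil replicate 3, where they passed (adjusted p = 0.00215, or 0.163 with an estimated correlation). DNA methylation and demethylation factors had a median of -0.13 and a mean of 0.02 (adjusted p = 0.400), with Uhrf1, the maintenance methylation cofactor, at 1.33 and Dnmt3a at -0.26. Uhrf1 ranked the 6 libraries as the mitosis gene Nusap1 did, and was not tested apart from the cell cycle shift. Oestrogen receptor targets had a median of -0.07 and a mean of 0.31 (adjusted p = 0.679), and glycolysis genes a median of -0.08 and a mean of 0.10 (adjusted p = 0.551). Stromal and endothelial markers had a median of -0.0086 and a mean of 0.29 (adjusted p = 0.979). In these last 4 lists camera pointed the way of the median.

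The first principal component, 46.5% of variance, placed oil replicates 1 and 2 at -47.3 and -70.8, oil replicate 3 at 9.6 and the tamoxifen libraries at 26.4 to 54.6. On this component every oil library lay below every tamoxifen library, and oil replicate 3 lay closer to the tamoxifen libraries than to the other oil libraries. Other measures were mixed. On the second component, 20.1% of variance, oil replicate 3 at -42 lay nearest oil replicate 2 at -22.8. By chi-square per degree of freedom these 2 were the most alike pair, at 32.6. The Pearson r of oil replicate 3 was 0.9731 with oil replicate 2 and 0.9839 with tamoxifen replicate 2.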

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

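The GC correction was chosen after seeing the data, and the other alternatives were fixed before. In edgeR, 0 genes passed with RLE or upper quartile factors, the filter of 1 CPM or the non-robust fit. The same held with the GC correction and with abundant transcripts left out, and limma-voom gave 0. The test against a log2 fold change of 0.5 also gave 0. That decides nothing, since it is stricter than the main test, which gave 0. Without a filter, 6 were higher, 5 of them at least 2-fold (Gstm5, Angptl2, Ddit4, Cebpa, Sostdc1 and Nrbp2 in all). DESeq2 gave 490 higher, 218 lower and 407 at least 2-fold, and Tet1 passed there at -0.66 (adjusted p = 0.0102, against 0.0797 to 0.599 in the other alternatives). Leaving out each library gave 0 to 2 higher genes, 0 to 2 of them at least 2-fold, and the 2, Car1 and Gm10273, came without oil replicate 3. The cause of these differences was not tested. The labels do not say that replicate numbers pair the samples. Deviations of same-numbered libraries correlated at -0.0325, 0.0709 and -0.251, which gives no sign of pairing but cannot exclude it. With the replicate block, 9 genes were higher, all 9 at least 2-fold. Median shifts of all genes between settings stayed at or below 0.0425.

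Gene lists past the threshold numbered 15 to 18 across settings and when each library was left out, but 0 with the correlation estimated and 1 in fry, for which the cause was again not tested. The fry count was 9 without oil replicate 3, 0 without any other single library and 0 with the replicate block, where the follicular list had an adjusted p of 0.149. The median of the follicular helper list ranged from 0.89 to 1.35 and that of the naive list from -0.26 to -0.16, past the threshold in camera with the preset correlation each time. Some values changed sign, none of them past the threshold as reported, and the cause was not tested. When each library was left out, Tet2 ranged from -0.0035 to 0.45, Cd74 from -0.72 to 0.31, Ctss from -0.42 to 0.0022, Cd7 from -0.12 to 0.11, Trdc from -0.0532 to 0.16, H2-Q7 from -0.26 to 0.0617, Themis from -0.0360 to 0.11, Col3a1 from -0.29 to 2.23, Sparc from -0.30 to 2.36 and Col1a2 from -1.43 to 0.86. The medians ranged from -0.23 to 0.17 for regulatory T cell genes, -0.0438 to 0.26 for interferon genes and -0.30 to 1.12 for stromal markers. Cd74 was 0.0117 in limma-voom. Cd7 was 0.0379 with upper quartile factors, 0.0241 with the filter of 1 CPM and 0.0461 with GC correction, and Themis was -0.11 with GC correction. The camera direction turned for glycolysis genes with GC correction (median -0.0678) and for stromal markers with the replicate block (0.14), abundant transcripts left out (-0.0067), GC correction (0.0637) and fry (-0.0086). Other medians that changed sign were activation genes (-0.08 without oil replicate 2), oestrogen targets (0.30 with no filter, 0.31 in DESeq2), DNA methylation factors and glycolysis genes (0.0170 and 0.0146 without oil replicate 1), p53 targets (-0.0086 without tamoxifen replicate 1), regulatory T cell genes (0.0077 with the filter of 1 CPM, 0.0163 in limma-voom, 0.0152 with the block, 0.0013 with GC correction) and stromal markers (0.0297 with upper quartile factors, 0.14 in limma-voom). Of the lists not past the threshold, activation genes passed with RLE, limma-voom, the block, abundant transcripts left out, GC correction, and without oil or tamoxifen replicate 3, but not with the correlation estimated (not run for limma-voom). Early response genes had 0 members past the threshold over the list alone with the block. Genes such as Sostdc1 and Rnf128, under 0.31 CPM in oil, rest on few counts.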

Other observations

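Of the tests below, the count of edgeR calls over other splits, the red cell precursor, memory and T cell share tests and the GC correction were chosen only after the results were seen. Rsad2, an interferon-induced antiviral gene, had 77.9, 37.9 and 113 CPM in tamoxifen and 17.7 to 22.7 CPM in oil (log2 fold change 1.90, SE 0.37, edgeR adjusted p = 0.257), although its list did not pass. It ranked the tamoxifen libraries as their share of haemoglobin did (1.3%, 0.546% and 2.09%), but not the oil libraries (0.25%, 0.56% and 0.468%). Rsad2 was not tested apart from red cell precursors. Rara, a retinoic acid receptor, had -0.59 (SE 0.11), Nrip1 -0.48 (SE 0.10) and the transcription factor Myb 0.69 (SE 0.13), each with an edgeR adjusted p of 0.257. Chosen after their values were seen, Ccl5, Gzmb and Gzmk were highest in oil replicate 3, at 59.7, 26.6 and 17.5 CPM, against at most 9.05, 3.31 and 3.81 CPM in the other libraries. The 18 memory and effector genes used below, a list chosen after results were seen, had a median of 0.645 (camera adjusted p = 0.000472, or 0.274 with an estimated correlation). The score of the anergy list followed theirs within groups (r of deviations 0.979, exact permutation p = 0.222 over 36 orders). Its group difference of 0.815 (SE 0.296) was 0.472 (SE 0.0802) with that score in the model and 1.21 (SE 0.287) without oil replicate 3, on which the slope rests.

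With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. DESeq2 gave 708 genes for the real split and at most 162 for another, so 1 of the 10 splits gave as many. edgeR gave 0 genes in each of the 10 splits, which decides nothing, since no count lies under 0. At an unadjusted p under 0.05 it gave 2145 genes for the real split and at most 1301 for another. For gene lists in camera with the preset correlation, the real split gave 16 and the highest other 16, and 3 of the 10 splits gave as many. With the correlation estimated, each split gave 0, the real one included, which again decides nothing.

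Cell cycle genes were higher with tamoxifen, in libraries where 18 red cell precursor genes, a list chosen after its values were seen, were also higher (median log2 fold change 2.26), both in camera with the preset correlation. With the correlation estimated neither passed (adjusted p = 0.240 and 0.172). Within groups the cell cycle score followed the precursor score (r of deviations 0.986, exact permutation p = 0.0278 over 36 orders). The group difference of 1.42 (SE 0.481) became 0.0193 (SE 0.167) with the precursor score in the model, but 0.43 (SE 0.125) without oil replicate 3. A candidate explanation for part of the difference is red cell precursors that passed a gate on CD4, CD25, CD44 and a further surface marker, with Aqp1 at 132 CPM and Sptb at 91.4 CPM in tamoxifen replicate 3. B cells or plasma cells stay open: with the B cell score the group difference was 1.19 (SE 0.744), from 0.201 to 1.79 when each library was left out, and 1.79 (SE 0.517) without oil replicate 3, over 2 SE above 0. Although a within-group r under 0.3 had been set to count against them, the r of 0.251 has a 95% interval of -0.811 to 0.928 over 6 libraries, a reading adopted after the value was seen. Proliferation of the T cells themselves was not tested apart from these.

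Follicular helper genes were higher with tamoxifen as a list in camera with the preset correlation, but not with it estimated (adjusted p = 0.161), and the call in fry ended without any 1 of 5 libraries. Memory and effector cells past the gate were scored by 18 genes outside the list. With that score in the model the group difference of 1.33 (SE 0.271) was 1.02 (SE 0.0668), and 1.64 (SE 0.232) without oil replicate 3. The slope on the score rests on oil replicate 3, and the r of deviations, 0.983, had an exact permutation p of 0.222 over 36 orders. The test therefore cannot decide on these cells, which stay open. Nor does a score without the list's genes bear on follicular helper cells past the gate. GC content is argued against as the whole cause, since the list's median was 0.985 after correction and 0.97 before. TET loss, tamoxifen and the reporter gate vary together here and stay open and untested.

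Naive and quiescence genes were lower with tamoxifen as a list in camera with the preset correlation, by a median of -0.20, but not with it estimated (adjusted p = 0.161) or in fry (adjusted p = 0.0918). The median was -0.216 after GC correction, which argues against GC content as the whole cause. It was -0.205 with haemoglobin, immunoglobulin, mitochondrial and most abundant genes left out. That setting moved all genes by a median of just -0.00487, since both fits used TMM factors, and other transcripts of other cells stayed in. It therefore cannot decide whether transcripts of other cells took reads. A lower share of T cells cannot be told apart from a change in the naive and quiescence genes. The reason is that 12 structural T cell genes had a median of -0.137 and a mean of -0.0916, with values from -0.27 to 0.20. The SE of that mean, 0.0461, was taken over the 12 genes and does not measure the spread between libraries. TET loss, tamoxifen and the reporter gate stay open and untested.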
